A study of Mus musculus with 4 samples.

How the data were processed

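RNA sequencing of sciatic nerves compared control mice with Zeb2 cKO mice at postnatal day 7. Per the labels, each sample was pooled nerve RNA extracted with Trizol, and libraries were made from total RNA with an Illumina TruSeq kit. The labels describe 2 samples per group. The 2 tables used here, 1 for each group, hold 1 library each, and the other sample of each group was not analysed here. The labels list each table under both samples of its group, so each table was assigned to its group and not to a numbered sample. No column of per-sample values was left unmatched.

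The authors processed reads with CASAVA, TopHat, Cufflinks and Cuffdiff on the mouse build mm9, per the submitters' processing notes, without tool versions. Whether bias correction was used is not given in the sources used here. Per the file headers, each table gives for every RefSeq transcript its locus, length in bases, coverage, FPKM and a quantification status. The FPKM values were computed by the authors with Cufflinks and are fragments per kilobase of transcript, scaled to the number of mapped fragments. The deposited coverage signal is the mean read depth per base and is not scaled to library size. Both tables list the same 28107 transcript rows under 22096 gene symbols. Rows with another status than OK in either library were left out (295 rows, 131 genes with no row left), and the FPKM of the remaining transcripts was summed for each symbol, which left 21965 genes. FPKM tables keep no whole read counts, so no count model was used.

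Depth was read from the coverage column. Coverage divided by FPKM had a median of 1.8724 in the control library and 1.2753 in the Zeb2 cKO library. These medians were taken over rows above 1 FPKM in both libraries. By their ratio the control library was 1.47 times as deep. Coverage times length of single-transcript genes above 2000 bases began at a cluster with a median of 52.6 bases (479 values, 10th to 90th percentile 46.6 to 60.2), which was taken as the contribution of 1 read. On that scale the tables hold an estimated 29729619 reads in the control library and 20288183 in the Zeb2 cKO library. Exact Poisson intervals on these estimated reads and Clopper-Pearson intervals on their ratio (95%) are quoted as counting intervals. They are approximate and cover counting error only, not the spread between animals, pools or libraries.

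Ratios were computed as log2((FPKM Zeb2 cKO + 1)/(FPKM control + 1)) for genes with a mean FPKM of at least 1. The pseudocount understates the change of low genes. Folds in the text are plain FPKM ratios. With 1 library per group no test between the conditions is possible, so no p-value is given and genes are described by a rule of size, a ratio of 2-fold or more on the pseudocount scale. In 33 gene lists fixed before the data were examined, the median ratio of the measured members was set against 10000 random lists of the same size drawn from genes in the same of 20 bins of mean FPKM. Of the 601 list entries, 591 matched a symbol in the tables, 8 matched through a RefSeq accession and 2 did not match, 1 of them because it was misspelled. The percentile describes these libraries, since genes are not independent replicates.

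Genes named in the text were Zeb2, the 12 highest and 12 lowest ratios among genes at 5 FPKM or more in the higher library, without immunoglobulin and T cell receptor segments and small RNA genes, the 3 largest absolute ratios of each list, and a few regulators and myelin genes named in advance. Xist, and members named because a count of 5 or fewer fell outside this rule (Me1, Elovl5, Erbb3, Zeb1, Nfatc4, Ngfr and Scn7a), and Egr3 as a member of both lists, were chosen after their values were seen. Some genes that the rule names are not reported here. The rule also asked to leave out genes with overlapping Cufflinks intervals. The tables hold no such intervals, so this part was not applied. A comparison with the second pair of libraries was planned and was not made. Positions are those of the tables on mm9, converted to count from 1. The length of 3284 rows equalled their converted span, and no row was 1 base longer or shorter. No strand of the reads was used here, so overlapping genes cannot be told apart.

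The alternatives were other pseudocounts, filters, scalings and fold thresholds, every status, and the top row of each symbol in place of the sum. Counts without small RNA genes or muscle markers, and lists without members that another list holds, were added after the data were examined. RefSeq names came from a table of another assembly, GRCm38.p6, of which no coordinates were used. Counting and list code was tested on simulated data of 12322 genes, with Poisson reads at the depths of both libraries. It counted 92 of 100 genes changed by 1.5 on the log2 scale, 100 of 100 changed by 3, and 0 of 12122 unchanged genes as 2-fold apart. Small RNA genes were left out, and changed genes were drawn from those at 2 FPKM or more in the control library. The simulation held counting error only, so it gives no rate of false calls for real pools. Of 200 unchanged simulated lists, 11 fell outside the percentiles 2.5 to 97.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.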

Results

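Sciatic nerves of control and Zeb2 cKO mice were profiled at postnatal day 7, when Schwann cells of the nerve are laying down myelin. Zeb2 encodes a zinc finger transcription factor, and cKO denotes a conditional knockout. The labels do not name the Cre line or the deleted exons. The comparison asks which transcripts of the developing nerve differ when Zeb2 is removed. The tables hold 1 control and 1 Zeb2 cKO library, each from pooled nerves, with an estimated 29729619 and 20288183 reads on RefSeq transcripts. There are no replicates behind any value below, so differences are described by their size, and counting intervals cover counting error only.

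Zeb2 (chromosome 2, 44839154 to 44968799, mm9) was at 34.4 FPKM in the control library and 19.5 FPKM in the Zeb2 cKO library, 0.568 of the control level (counting interval 0.548 to 0.588). The direction was that of the labels. The tables hold 1 Zeb2 transcript, quantified over all of its exons, so reads from undeleted exons and from cells that kept the gene are counted with it. Gm13476 and Mir5129 overlap the Zeb2 locus.

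Of 12903 genes measured, 1109 were 2-fold or more higher and 806 were 2-fold or more lower in the Zeb2 cKO library, and 10988 lay within 2-fold. The median gene had a log2 ratio of 0.18. With the Zeb2 cKO FPKM scaled down by this median, here called rescaling to the median gene, the split was 807 higher and 940 lower. The pseudocount was added after the scaling, so the median was then 0.02 and not exactly 0. Rows of microRNA and small nucleolar RNA genes, which are short and poorly captured in such libraries, made up 61 of the higher and 72 of the lower genes. Without them the counts were 1048 higher and 734 lower. Leaving out only the 17 listed skeletal muscle markers, all of them lower, gave 1109 higher and 789 lower. Other genes that muscle expresses stay in that count, so it does not measure how many lower genes come from muscle.

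**Figure D1:**
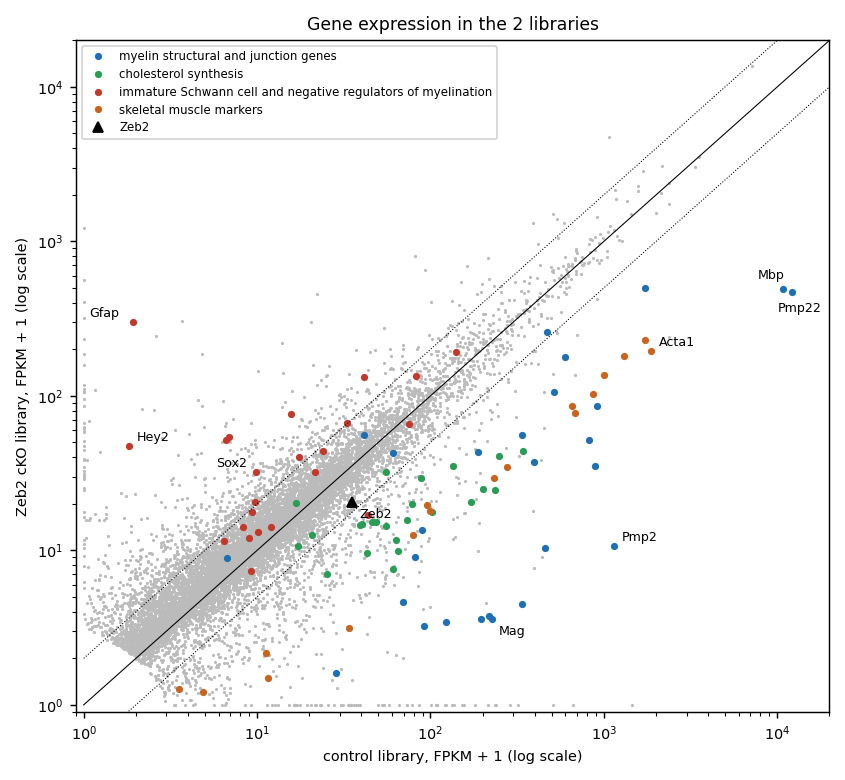
Expression of each measured gene in the control library (x axis, FPKM + 1, log scale) against the Zeb2 cKO library (y axis, FPKM + 1, log scale); grey points are genes, coloured points are members of 4 fixed lists (myelin blue, cholesterol synthesis green, immature Schwann cell red, skeletal muscle orange), the black triangle is Zeb2, the solid line marks equality and the dotted lines 2-fold. Mbp and Pmp22 lie far below the dotted lines at 488 and 471 FPKM in the Zeb2 cKO library, Gfap and Hey2 far above them.

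Genes of the myelin sheath were lower in the Zeb2 cKO library almost throughout. Pmp22, a structural protein of compact peripheral myelin (chromosome 11, 62945012 to 62973048), was at 12153 FPKM in the control library, the highest of the quantified genes there, and at 471 FPKM in the Zeb2 cKO library, 25.8-fold lower. Mbp, myelin basic protein (chromosome 18, 82644515 to 82755029), was at 10825 and 488 FPKM, 22.2-fold lower. Of 27 measured members of the myelin list, 23 were 2-fold or more lower and 0 were 2-fold or more higher. The median log2 ratio was -3.91, and 0 of 10000 random lists of matched expression had a median as low. Together the list took 8.17% of the estimated reads in the control library and 0.579% in the Zeb2 cKO library. The 17 skeletal muscle markers, described with the lipid genes, were lower as well, with a median of -2.91.

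Among genes at 5 FPKM or more in the higher library, without small RNA genes and immune receptor segments, the 12 lowest ratios were led by myelin genes. Pmp2, the myelin fatty acid-binding protein (chromosome 3, 10179851 to 10183885), was at 1145 FPKM in the control and 9.63 FPKM in the Zeb2 cKO library, 119-fold lower. Mag, the myelin-associated glycoprotein that faces the axon (chromosome 7, 31684202 to 31699851), was 86.8-fold lower, from 224 to 2.58 FPKM. Fa2h and Ugt8a, enzymes of myelin galactolipid synthesis, were 74.8-fold and 48.6-fold lower. A330049M08Rik, whose RefSeq accession is that of Ncmap, a protein of noncompact myelin, was 96.1-fold lower, Dusp15, a phosphatase, 79.2-fold lower, and Pllp, the proteolipid plasmolipin, 54.9-fold lower. Fam178b and Emid1 were 59.3-fold and 58.7-fold lower, and 2310046A06Rik, which the myelin list held as Mlip and which muscle also expresses, 49.2-fold lower. The last of the 12, LOC100302567, is a short row on chromosome 7 (29136559 to 29136652) that overlaps Rps16, at 30.4 FPKM in the control library and listed at 0 in the other. Small RNA genes were left out by symbol only, so a short row under another name was not covered.

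Cholesterol synthesis genes were lower as a group in the Zeb2 cKO library. Idi1, an isomerase of the pathway, was at 235 FPKM in the control and 23.8 FPKM in the Zeb2 cKO library, 9.88-fold lower. Of 24 measured members, 20 were 2-fold or more lower and 0 higher, with a median log2 ratio of -1.95 and 0 of 10000 random lists as low. Fatty acid and sphingolipid synthesis was split. Of 21 members, 10 were 2-fold or more lower, among them Elovl6 (11.5-fold), Gal3st1, the sulfotransferase that makes sulfatide (6.42-fold), and Elovl1 (4.22-fold), which overlaps Cdc20. The members Me1 and Elovl5 were 3.53-fold and 3.36-fold higher. The median was -0.90, again below all 10000 random lists. Beside these groups, the 17 skeletal muscle markers were all 2-fold or more lower as well, with a median of -2.91. Acta1, skeletal muscle actin, was at 1879 FPKM in the control and 193 FPKM in the Zeb2 cKO library (9.73-fold), Tnni2, a troponin, was 8.95-fold lower and Myh1, a fast myosin, 15.5-fold lower.

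Regulators of the Schwann cell lineage went in both directions. Pou3f1, a transcription factor of promyelinating Schwann cells (chromosome 4, 124334889 to 124337899), was at 68.1 FPKM in the control and 1.02 FPKM in the Zeb2 cKO library, 66.6-fold lower, and was among these 12 lowest ratios. Egr2, the transcription factor that drives myelin genes, was 6.21-fold lower, from 54.5 to 8.79 FPKM, and Itga6, a laminin receptor subunit, 5.78-fold lower. Sox10, which marks the lineage at all stages, was at 139 and 69.2 FPKM. It was 2.01-fold lower by FPKM, and just short of 2-fold with the pseudocount. Of 20 measured members of this list, 4 were 2-fold or more lower, with the neuregulin receptor Erbb3 (3.01-fold) as the remaining one, and 2 were higher, Zeb1 (2.56-fold) and Nfatc4 (2.57-fold). The median was 0.14, at percentile 54.1 of the random lists, and the mean was -0.40. That median became -0.03 after rescaling to the median gene.

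Genes of immature Schwann cells and negative regulators of myelination were higher as a group. Gfap, an intermediate filament of immature and nonmyelinating Schwann cells (chromosome 11, 102748650 to 102758514), was at 0.914 FPKM in the control and 300.1 FPKM in the Zeb2 cKO library, 329-fold higher (counting interval 266 to 410). Hey2, a transcriptional repressor downstream of Notch (chromosome 10, 30552165 to 30562589), was 56.0-fold higher, from 0.829 to 46.4 FPKM. Cdh2, N-cadherin, was 9.03-fold higher. Sox2, a transcription factor of immature Schwann cells (chromosome 3, 34548927 to 34551382), was 3.51-fold higher, from 8.87 to 31.2 FPKM, and its locus is shared with Sox2ot. Jun and Ednrb, the endothelin receptor, stayed within 2-fold with log2 ratios of 0.88 and 0.70. Of 23 measured members, 10 were 2-fold or more higher and 1, the neurotrophin receptor Ngfr, was 2.71-fold lower. The median was 0.88, and 0 of 10000 random lists were as high. Over the 4 members that no other list holds it was 0.75, at percentile 96.8. Immediate early genes, which respond to handling of tissue, had a median of 0.87, above all 10000 random lists, and Jun, Egr1 (9.01-fold higher) and Egr3 are in both lists.

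Lists that share members with it also had higher medians. In the list of nonmyelinating Schwann cell genes, 7 of 12 members were 2-fold or more higher, including Ncam1, a neural cell adhesion molecule (5.17-fold), and 2, Ngfr and the sodium channel Scn7a, were lower, with a median of 1.52. In the repair cell list, 5 of 10 were higher and 1, Ngfr, was lower, with a median of 0.98, and the largest ratios beside Gfap were in Tnc, tenascin C (7.08-fold), and Ccl2 (5.36-fold). The median was 1.70 over the 7 members at a mean FPKM of at least 5. The repair cell list named 20 genes, and only these 10 were measured. Other lists hold 9 of the 10 measured members, so no value without shared members is given. The median therefore says little about genes that only the repair cell list holds.

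Under the same limits, the 12 highest ratios besides Gfap and Hey2 included 3 genes above 100 FPKM in the Zeb2 cKO library whose control level was under 3 FPKM. Slc1a3, a glial glutamate transporter, was at 306 FPKM, 114-fold higher. Aldh1a1, an enzyme of retinoic acid synthesis, was at 244 FPKM, 153-fold higher, and Csn3, kappa-casein, at 107 FPKM, 653-fold higher with a counting interval of 348 to 1404, since the control value rests on about 9 reads. Prss35, a serine protease family member, was at 185 FPKM and 48.2-fold higher. Smoc1, a matrix protein whose locus overlaps Mir3067, was 68.8-fold higher, Col9a1, a collagen chain, 51.8-fold higher, and Mmd2 26.1-fold higher. Zpld1 and Expi, at 68.1 and 42.6 FPKM in the Zeb2 cKO library, rest on about 6 and 5 reads in the control library, and were 976-fold (counting interval 459 to 2550) and 174-fold (72.6 to 561) higher. Agr3 was at 37.4 FPKM in the Zeb2 cKO library against about 1 read in the control library, a ratio of 909 with a counting interval of 184 to 21334.

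**Figure D2:**
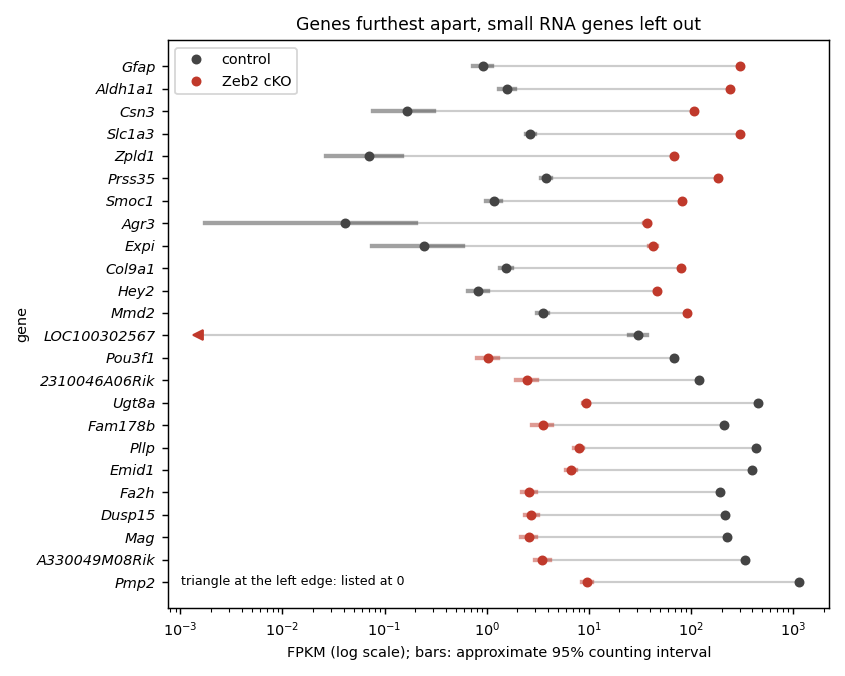
FPKM (x axis, log scale) of the 12 highest and 12 lowest ratios among genes at 5 FPKM or more in the higher library, without small RNA genes and immune receptor segments, in the control and the Zeb2 cKO library; points are single libraries (control dark grey, Zeb2 cKO red), the triangle is a gene listed at 0, thick bars approximate 95% counting intervals, and thin grey lines join the libraries. Gfap runs from 0.914 to 300.1 FPKM and Pmp2 from 1145 to 9.63 FPKM.

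Signalling, matrix and cytokine lists also had medians above that of all genes. In the Notch list, 6 of 24 members were 2-fold or more higher and 0 lower. Besides Hey2 these included the ligand Jag1 (4.51-fold) and the coactivator Maml2 (3.86-fold). The median was 0.43, and 81 of 10000 random lists were as high. It was 0.36 over the 20 members that no other list holds (percentile 94.4). In the BMP and TGF-beta list, 6 of 26 were higher and 0 lower, including the receptor Acvr1 (6.10-fold), the ligand Tgfb2 (5.57-fold) and Id3, an inhibitor of basic helix-loop-helix factors (3.25-fold), with a median of 0.71. In the Wnt list, 10 of 21 were higher, including the receptor Fzd2 (3.35-fold) and the secreted antagonist Sfrp4 (3.24-fold). Nkd1, an inhibitor of Wnt signalling, was 6.26-fold lower, and the median was 0.90. For both of these lists 0 of 10000 random lists were as high. In the list of matrix genes, 6 of 26 were higher, led by Col12a1 (10.7-fold), Tnc and Col18a1 (5.46-fold), with a median of 0.46. Fibroblast markers, given with the other cells of the nerve, had a median of 1.05. Among 9 measured cytokines and chemokines, 4 were higher, with Ccl2 and Ccl7 (3.43-fold) the highest, and Il34 was 3.73-fold lower. The median was 0.99. It was 0.19 over the 7 members that no other list holds (percentile 57.7) and 0.59 over the 8 at a mean FPKM of at least 5. Among 12 interferon-stimulated genes, with a median of 0.43, 0 reached 2-fold, and Ddx58, Rtp4 and Oasl2 had the largest log2 ratios, 0.92, 0.77 and 0.75. That median was at percentile 93.0, and was -0.0041 over the 6 members at a mean FPKM of at least 5.

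Cell cycle genes did not reach 2-fold. In the S phase list 0 of 20 members and in the G2 and M phase list 0 of 24 members were 2-fold apart, with medians of 0.35 (percentile 93.1) and 0.44 (percentile 99.1). With the top transcript of each symbol the latter was 0.39 (percentile 96.3). The largest log2 ratios were 0.84 for Rrm2, 0.82 for Slbp and 0.59 for Tipin, and 0.77 for Kif23, 0.67 for Prc1 and 0.66 for Bub1b. Genes of the HDAC and NuRD corepressor complexes had a median of 0.14 (percentile 57.1), which became -0.04 after rescaling. Chd3 alone of 15 was 2-fold apart, at 2.22-fold higher, and did not keep that size after rescaling (log2 ratio 0.92). Ctbp2 and Hdac2 had log2 ratios of 0.99 and 0.47.

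Markers of other cells of the nerve differed between the libraries to unequal extents. Perineurial markers were 2-fold or more higher for 10 of 11 members, with a median of 1.47, led by Moxd1 (11.7-fold), the tight junction protein Cldn1 (5.58-fold) and Dleu7 (5.29-fold). Of 13 fibroblast markers, 8 were higher, with a median of 1.05, including Etv1 (3.19-fold) and the proteoglycans Dcn (2.62-fold) and Lum (2.48-fold). For both lists 0 of 10000 random lists were as high. Endothelial markers had a median of 0.66 with 0 of 15 members at 2-fold, and Sox18, Plvap and Tek were highest at 0.99, 0.98 and 0.85. In the pericyte and smooth muscle list, with a median of 0.54, Cspg4 and Rgs5 were 2.15-fold and 2.07-fold higher, while Des, desmin, which skeletal muscle also expresses, was 5.05-fold lower. Cspg4 and Rgs5 did not keep 2-fold after rescaling to the median gene (log2 ratios 0.86 and 0.85). Adipocyte markers had a median of 0.95, with Cfd, Fabp4 and Adipoq 2.62-fold, 2.42-fold and 2.43-fold higher, Adipoq not after rescaling (0.98). Mast cell markers had a median of 0.98, with Mcpt4 and Cpa3 2.22-fold and 2.32-fold higher, neither of them 2-fold after rescaling (both 0.90), and Cma1 at a log2 ratio of 0.98. Macrophage markers had a median of -0.02 with 0 of 16 members at 2-fold, and the largest log2 ratios were 0.52 for Cd163, 0.49 for Lyz2 and 0.47 for Itgam. The neutrophil and erythroid list had a median of 0.27, and of 1.06 over the 5 members at a mean FPKM of at least 5, with Alas2 3.20-fold, Hbb-b1 4.18-fold and Hba-a1 2.10-fold higher, the last not 2-fold after rescaling (0.87). The globin values are uncertain, since Hbb-b2 and Hba-a2 are near-identical copies that overlap them in the tables. Neuronal transcripts had a median of 0.04, which became -0.08 after rescaling, and Gap43, Uchl1 and Tubb3 had log2 ratios of 0.82, -0.59 and -0.56. Melanocyte markers, which include Sox10, had a median of -0.92, and of -1.62 over the 3 members that no other list holds, and Pmel, which overlaps Dgka, and Dct were 7.06-fold and 9.37-fold lower. Of the 11 T and B cell markers, 0 reached a mean of 1 FPKM.

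**Figure D3:**
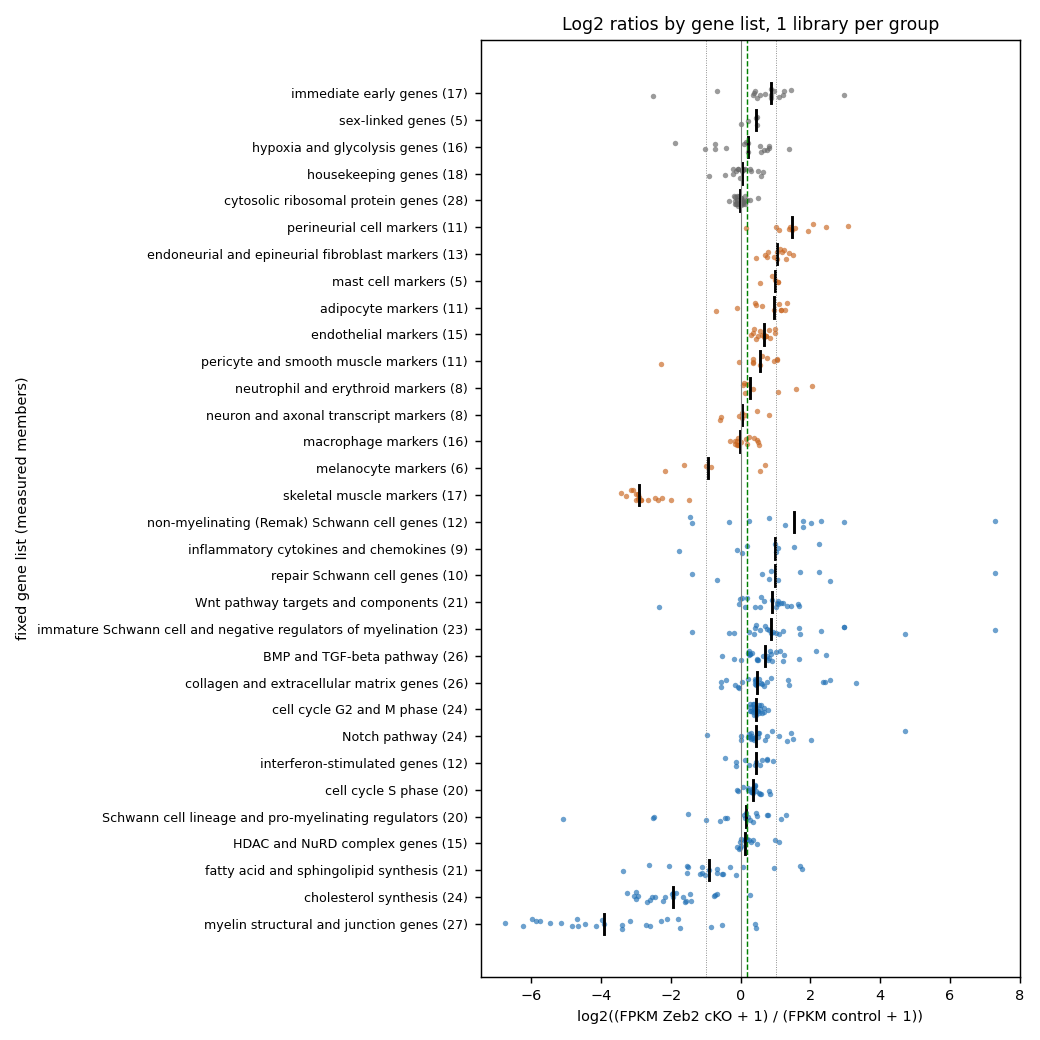
Log2 ratio of FPKM + 1, Zeb2 cKO over control (x axis), of each measured member of the fixed gene lists (y axis, number of measured members in brackets); points are genes, coloured blue for programs, orange for cell type markers and grey for quality lists, black bars are list medians, dotted lines mark 2-fold and the dashed green line the median gene at 0.18. Myelin genes have a median of -3.91 and perineurial markers a median of 1.47.

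Lists that describe the libraries differed less, apart from immediate early genes. Ribosomal protein genes had a median of -0.02 with 0 of 28 at 2-fold, and Rps23, Rplp0 and Rps14 were furthest from 0 at 0.50, -0.35 and 0.27. Housekeeping genes had a median of 0.04, which became -0.14 after rescaling, with Gapdh at -0.92, B2m at 0.64 and Pgk1 at 0.58. Hypoxia and glycolysis genes had a median of 0.21, with Ndrg1 3.69-fold and Aldoa 2.04-fold lower and Slc2a1 2.68-fold higher. Immediate early genes had a median of 0.87, above all 10000 random lists, with Egr1 9.01-fold and Fosb 6.18-fold higher. The Y-linked genes Uty, Ddx3y and Eif2s3y had log2 ratios of 0.48, 0.47 and 0.45, and the list had a median of 0.45. Xist was at 35.7 FPKM in the control and 36.0 FPKM in the Zeb2 cKO library.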

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

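No paired analysis was possible because the tables hold 1 library of each group, and for the same reason no library could be left out. A requirement that Cufflinks intervals do not overlap was not run, as the tables used here hold none. In its place, and chosen after the data were examined, an overlap of counting intervals was tried, which removed 0 of the 1915 genes counted as 2-fold apart. At this depth, counting intervals of genes already 2-fold apart with the pseudocount could hardly overlap. That setting therefore could remove few genes and says little about the counts. The counts depended mainly on the pseudocount and the threshold. With a pseudocount of 5 FPKM they were 477 higher and 529 lower, 1006 in all, and with 0.1 FPKM 1558 higher and 908 lower, 2466 in all. At a 1.5-fold threshold they were 2537 and 1266, 3803 in all, and at 3-fold 401 and 457, 858 in all. With a mean FPKM of at least 5 the higher count was 739. The 2 settings that rescale the FPKM by the median or the trimmed mean of the ratios each gave 807 higher and 940 lower. Which direction prevails therefore depends on the scaling. Among the lists, the neutrophil and erythroid median became 1.06 (percentile 99.7) at a mean FPKM of at least 5, where 5 members remained, and the G2 and M phase median became 0.39 (percentile 96.3) with the top transcript of each symbol. The repair cell median was 1.45 with a pseudocount of 0.1, 1.44 with the top transcript and 1.70 at a mean FPKM of at least 5, where the cytokine median was 0.59. Rescaling to the median gene lowered list medians by about its shift of 0.18, the Notch, matrix and G2 and M phase medians to 0.27, 0.27 and 0.28. Without members that another list also holds, a setting chosen after the data were examined, the immature Schwann cell list kept 4 members with a median of 0.75 (percentile 96.8), the Notch list 20 with a median of 0.36 (percentile 94.4), and the cytokine list 7 with a median of 0.19 (percentile 57.7), and the melanocyte list 3 with a median of -1.62. The percentile of the immature Schwann cell and Notch lists was lost with fewer members and a similar median, while the cytokine median itself was much smaller. Zeb2 stayed lower and within 2-fold under the pseudocount of 0.1 and the median scaling. No named gene changed direction under either, though 2 came to pass 2-fold and 7 (Chd3, Mcpt4, Cpa3, Hba-a1, Cspg4, Rgs5 and Adipoq) ceased to under the median scaling, and 8 came to pass it with the pseudocount of 0.1. The median scaling changed the sign of 4 list medians that were 0.14 or less, and the top transcript that of the neuronal list. At a mean FPKM of at least 5 the interferon-stimulated median went from 0.43 to -0.0041, over the 6 of 12 members left. The cause was not tested. Depth limits the low end: about 35.6 reads in the control and 24.2 in the Zeb2 cKO library make 1 FPKM over 1 kilobase.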

Other observations

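All groupings and tests in this part were chosen after the ratios had been seen. Gene families taken from their symbols (16 families looked at) show further groups. Of 26 measured Hox genes, which encode positional identity, 13 were 2-fold or more higher in the Zeb2 cKO library and 0 lower, with a median log2 ratio of 0.98. Hoxb9 went from 1.32 to 15.2 FPKM. Of 35 collagens, 15 were higher and 1, Col23a1, was lower, and the largest ratios were in Col9a1, Col11a1 (21.3 to 458 FPKM) and Col9a3 (13.0 to 220 FPKM). Among 20 integrins, Itga6 was lower while 6 others, including Itgb3, Itga1 and Itgb8, were higher. Sox3, a relative of Sox2, went from 0.87 to 12.2 FPKM, and among forkhead genes Foxd1 went from 7.04 to 44.2 FPKM and Foxs1 from 16.9 to 69.4 FPKM.

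Potassium channels, semaphorins and cadherins were among the families with several members 2-fold or more apart on both sides. Members at low values were counted too, such as Cdh15 (1.96 to 0.21 FPKM) and Kcnc4 (1.90 to 0.15 FPKM). Loss of muscle RNA was not examined for these families. Kcna1 and Kcna2, voltage-gated channels, were lower, from 83.9 to 4.90 and from 19.9 to 3.38 FPKM. Kcnn4 and Kcnh2 were higher, from 1.57 to 21.7 and from 3.74 to 18.1 FPKM. Of 17 semaphorins, 5 were lower, including Sema4g and Sema6c, and 6 were higher, including Sema3d, Sema6a and Sema3c. Cdh1, E-cadherin of noncompact myelin, was lower (43.0 to 10.6 FPKM), whereas Cdh2 and Cdh10 were higher. Fgf1 was at 72.0 and 17.0 FPKM.

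The lower myelin genes are the largest group pattern. Less muscle in the Zeb2 cKO library cannot be the whole cause, because 17 of the 27 measured myelin genes were lower than every muscle marker above 100 FPKM, the lowest of which had a log2 ratio of -3.28 without a pseudocount, and 12 were lower than every muscle marker of any level (lowest -4.40). Fewer Schwann cells alone would lower other lineage genes alike. For 12 such markers outside the myelin list, 9 of them held by another list, the median was 0.53. Their lower quartile was -1.09 (-1.39 with the 4 markers that a first draft of 16 also held, 2 of them myelin list members), against an upper quartile of -2.22 for the myelin genes. Of the 12, 7 were higher and 5 lower, among the latter Sox10 and Erbb3 at 0.498 and 0.333 of the control level. The higher ones include Dhh, Cdh19, Fabp7 and Ednrb, which the immature Schwann cell list also holds. Their median therefore does not measure the number of Schwann cells, and a smaller loss of these cells stays open. The scaling to the library total does not account for the lower myelin genes, since their median was -4.05 after rescaling to the median gene. A change of state in Schwann cells is a candidate explanation that stays open and untested with 1 library per group, as does any other difference between these pools, and for the cholesterol genes, of which 1 of 24 was lower than every abundant muscle marker, loss of muscle RNA stays open too.

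The lower skeletal muscle genes are consistent with muscle carried over at dissection in unequal amounts. The 9 markers at 100 FPKM or more in the control library were lower by a nearly common factor, 7.31-fold to 9.73-fold, with an SD of log2 ratios of 0.14, against 1.91 for the 19 myelin genes of that abundance. Less abundant markers differed more, with a lowest log2 ratio of -4.40. Other genes that muscle expresses would be lower for that reason as well, Aldoa and Des possibly among them. An effect of genotype on muscle was not tested.

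Perineurial and fibroblast markers were higher, and a lower share of Schwann cell and muscle RNA would raise every other cell type alike. That was not seen: all 9 perineurial markers held by no other list, with log2 ratios from 1.12 upward without a pseudocount, lay above each of the 16 macrophage markers, which reached at most 0.82. Of 10 such fibroblast markers 9 did, with a lower quartile of 1.00. The macrophage list was itself low (percentile 4.66 of the random lists), and fewer macrophages would give the same contrast. These 9 perineurial markers also lay above every endothelial marker held by no other list (highest 1.04). For them, a rise equal to that of endothelial cells cannot be the whole cause. Fibroblast, adipocyte and mast cell markers reached 1.68, 1.42 and 1.21, above the lowest of the 9, so their ranges overlapped. The lowest of all 11 perineurial markers, which another list also holds, had a log2 ratio of 0.15 with the pseudocount. For the fibroblast markers a shared rise stays open, since their median of 1.19 was close to that of adipocyte (1.27) and mast cell markers (1.10). Other open explanations are more sheath tissue in the Zeb2 cKO pool, which may also bear on the higher adipocyte, collagen and Hox genes, and a change in these cells or in Schwann cells that use the same genes.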
